A study of Drosophila melanogaster with 26 samples.

How the data were processed

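Nascent transcription was measured by PRO-seq, a run-on assay that reads the RNA held by engaged RNA polymerase, in 26 libraries of the Drosophila melanogaster cell line S2. Per the labels' protocols, cells of 6 lines received water (mock) or 500 µM auxin for 6 hours, nuclei were isolated, and human HCT116 cells, 5% of the total, were added as a spike-in at permeabilisation. After biotin enrichment, ligation of RNA adapters and removal of the cap, the cDNA was amplified by PCR and sequenced from a single end. The design text calls the replicates biological. Groups were taken from the sample titles: 2 libraries for each line and treatment, and 3 for each treatment of the line with tagged Ino80. Table columns named Parental were matched to the S2_OsTir1 line, the only line without a tag in the labels.

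The deposited counts are whole numbers of reads per transcription start site (TSS). Each TSS is represented by a strand-specific window of 150 bp on genome build dm3, and 14517 of the 17118 windows are marked in the deposited annotation as defined from CAGE, a method that maps capped 5' ends. Per the submitters' processing notes, cutadapt 1.18, Bowtie 0.12.9 and DESeq2 1.22.2 were used with build dm3. The role of each tool, the read end that was counted, and the treatment of duplicates and of reads with several matches are not given in the sources used here. On the same strand 75 windows overlap a neighbour, so their reads may be shared. Spike-in counts were not used here, so that every change below is relative to the other TSSs of the same library, and a change of total transcription would not be seen.

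The deposited annotation also gives, per TSS, a gene, a class (developmental or housekeeping), one of 9 promoter clusters and, per the labels of its columns, a match score from 0 to 100 for each of a set of core promoter motifs. How the score was computed is not given in the sources used here. The class and cluster were used as deposited and were not derived again. Gene names are those of the table. Newer symbols, given in brackets or used alone for genes listed only by number, came from a dm6 annotation that matched 13242 genes by identifier and was used for names only. All coordinates are 1-based positions on dm3 as deposited.

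Counts were analysed in R 4.3.3. TSSs were kept by edgeR's filterByExpr on the 12 groups, which left 10425 TSSs of 8306 genes out of 17118 TSSs of 13500 genes. Of those kept, 3301 were developmental, 5976 housekeeping and 1148 unclassified. Libraries were scaled with TMM factors, and edgeR 4.0.16 fitted one quasi-likelihood model with robust dispersion to all 26 libraries as 12 group means, with 14 residual degrees of freedom and a common biological coefficient of variation of 0.164. With 2 libraries per group, a fit of one line alone has few residual degrees of freedom, and the shared fit assumes that lines vary alike. Contrasts were auxin against mock in each line, the same contrast beyond that of the parental line, the Snr1 effect against the Brd7 effect and against the Ino80 effect, and each mock line against the parental mock. Adjusted p-values are Benjamini-Hochberg values over all TSSs tested, from edgeR's quasi-likelihood F-test unless another tool is named, and a TSS is said to have risen or fallen, or to be called, at an adjusted p under 0.05. Fold changes are log2 of auxin over mock as fitted, with their standard error. Levels are TMM-normalised CPM, counts scaled to the size of the library, as mean ± SD over the libraries of a group.

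Gene lists were tested with camera in limma 3.58.1 on voom values of the same model, with a preset correlation between genes of 0.01, one TSS per gene (that with the highest mean CPM) and Benjamini-Hochberg adjustment over 108 tests, 18 lists in 6 lines. Beside it stand camera with an estimated correlation, under which the preset calls of all 61 list tests were lost, and counts of members called over all TSSs tested and adjusted over the list alone. The lists were cytosolic ribosomal proteins, mitochondrial ribosomal proteins, proteasome, aminoacyl-tRNA synthetases, oxidative phosphorylation, basal transcription and splicing, DNA replication and S phase, mitosis, heat shock, amino-acid and endoplasmic reticulum stress, ecdysone response, immune response, JNK and apoptosis, hemocyte and extracellular matrix, signalling targets, developmental transcription factors, cell surface and cytoskeletal regulators of development, and chromatin remodellers. Markers of neuron, muscle, fat body, ovarian somatic cell, germ line, epithelium and hemocyte, the lineage of S2 cells, were described without a list test. The 2 promoter classes were compared by camera in the same way, with adjustment over 6 lines, and by Fisher's exact test on the TSSs called. The lists, their tests, the class tests and the rule for named genes were set before the data were examined, as were the alternatives apart from those stated to be added later.

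Named genes are the gene of each tagged protein and, per line, the 10 with the largest rise and the 10 with the largest fall among TSSs called at an adjusted p under 0.05. All auxin libraries of such a gene had to lie on one side of all mock libraries, with a mean of at least 5 CPM and a symbol other than a CG number. From each list with a called member, up to 4 called members by size of change were added, with values in other lines where useful. Of these, the text gives mainly genes whose call held without each single library of the line, and the others as counts. For genes with 1 to 3 counts over the auxin group the ratio of pooled counts is given with its exact 95% interval, and genes with 0 counts there are left unnamed. List medians are given also with such genes set to a floor of 3 counts over the group. Reads carried no molecular identifiers in the sources used here, so intervals and floors cover counting error only.

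Total counts ran from 997810 to 4999044 per library, and the 10 highest TSSs took 1.74% to 3.03% of them. No libraries were duplicates: replicates of a group differed by 1.83 to 12.58 times the counting noise (chi-square per degree of freedom), with r between 0.954 and 0.99 across TSSs on the log2 CPM scale. The model was tested on simulated data, counts drawn from the real means, library sizes and dispersion with 200 changed genes. Of genes changed 4-fold, 72.7% to 87.9% were recovered per line, of 2-fold changes 34.3% (parental) to 59.7% (Ino80), and of 1.5-fold changes 7.5% to 17.9%, with 2 to 6 false calls among at least 10126 unchanged TSSs.

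The titles number the replicates, and whether equal numbers pair a mock with an auxin library was checked before calls were compared, by correlating deviations from the group means. In the Ino80 line the 3 pairs had r of 0.576, 0.245 and 0.261, all over 0.1, so its numbers were taken to pair libraries. This comes from the data and not from a label, and replicate 2 correlated better with another number. Ino80 calls, in all and per class, cluster and list, are given also with the pair as a block where their number changes by over 1.5 times. Overlaps, correlations and counts adjusted over the list alone were not run with it. The other lines have 2 pairs and share only a number.

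Alternatives were DESeq2 size factors, library size alone, no filter or a stricter filter at a mean of 2 CPM, the DESeq2 1.42.0 Wald test, the libraries of one line alone, the replicate block, counts summed per gene, camera with an estimated correlation, and each library left out in turn. Leaving out a library leaves 1 in its group, which is then assumed to vary like the other groups. Replicates 2 and 3 of the Ino80 line alone, and for results other than counts of calls the settings that had been planned only for those counts, were added after seeing the data. Scaling to spike-in totals was not run.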

Results

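PRO-seq libraries were compared from S2 cells, a Drosophila line of hemocyte origin, after the rapid loss of single chromatin remodelling proteins. All 6 lines expressed OsTir1, a plant protein that directs the destruction of proteins carrying an auxin-inducible degron (AID) once auxin is added. In 5 lines a remodeller protein carried the AID tag: Snr1, a core subunit of the Brahma (SWI/SNF) complexes; Brd7, a bromodomain protein of Brahma; the ATPases Iswi and Ino80; and Chd1. The parental S2_OsTir1 line carried no tag. Each line was compared after 6 hours of 500 µM auxin with its own mock libraries, 2 against 2, or 3 against 3 for Ino80. The title of the series sets developmental against housekeeping programs, which gives the question put to each line: which genes lose or gain transcription without the protein, and whether they belong to one class of promoter.

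In the parental line the total counts over all TSSs were 1166981 and 1085780 for mock libraries 1 and 2, and 1161077 and 2180826 for auxin libraries 1 and 2. In the same order the totals were 3132992, 3128237, 2999360 and 2761883 in the Snr1 line, and 4999044, 4140969, 3512539 and 3993609 in the Iswi line. They were 4107119, 4147617, 4428783 and 4552180 in the Chd1 line, and 3537092, 2934335, 2992840 and 3579715 in the Brd7 line. The Ino80 mock libraries held 1712513, 2872038 and 2129228 counts and the auxin libraries 2722407, 997810 and 3438432. Over all libraries the first principal component took 32.1% of the variance and the next 18.4%. In what follows, values after ± are SDs of CPM or standard errors of log2 fold changes, and windows are given by chromosome, start and end on dm3.

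The genes of the tagged proteins were read first in their own lines. Snr1 (chromosome 3R, 1296667 to 1296816) had 46.4 and 31.5 CPM in the mock libraries and 57.0 and 54.2 CPM with auxin, a change of 0.51 ± 0.20 (adjusted p = 0.0644) that was called with library size alone (0.0136) and without mock 1 (0.0231). Iswi (chromosome 2R, 8524179 to 8524328) rose from 64.1 and 57.3 CPM to 101 and 87.1 CPM (0.63 ± 0.17, adjusted p = 0.0241). That call was lost without auxin library 1 (0.52, adjusted p = 0.239) or mock library 2 (0.54, adjusted p = 0.233), with library size alone (0.064) and in this line alone (0.178). Ino80 (chromosome 3R, 15228654 to 15228803) had 53.05, 59.8 and 56.5 CPM in the mock and 48.6, 50.7 and 45.1 CPM in the auxin libraries (−0.24 ± 0.17, adjusted p = 0.453). Chd1 (chromosome 2L, 2987569 to 2987718) had 83.4 and 100 against 80.2 and 107 CPM (0.03 ± 0.17, adjusted p = 1). Brd7 was taken to be CG7154 (Brd7-9; chromosome 2L, 7782869 to 7783018), with 62.4 and 66.2 against 68.2 and 73.4 CPM (0.14 ± 0.25, adjusted p = 0.843). The degron removes protein, so nascent RNA of these genes does not show whether depletion succeeded.

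Auxin itself was tested in the parental line, where no TSS was called: edgeR called 0 of 10425 and the DESeq2 Wald test called 3, with 484 (4.6%) at an unadjusted p under 0.05. The 3 TSSs, chosen after their values were seen, were lower: CG34115 (−1.05, adjusted p = 0.0334), Mocs1 (−0.65, adjusted p = 0.0334) and MP1 (−0.76, adjusted p = 0.00126), all by DESeq2. As lists, camera placed aminoacyl-tRNA synthetases (median log2 fold change 0.23), mitosis genes (0.17) and basal transcription and splicing (0.13) above the other genes, with adjusted p = 0.000344, 0.00752 and 0.0102. It placed cytosolic ribosomal proteins (−0.08), immune genes (−0.14), amino-acid and endoplasmic reticulum stress genes (−0.08) and heat shock genes (−0.17) below them, with adjusted p = 0.00307, 0.0139, 0.0186 and 0.0285. With an estimated correlation these became adjusted p = 0.102, 0.639 and 0.551 for the higher lists and adjusted p = 0.634, 0.599, 0.535 and 0.559 for the lower ones. Adjusted over the list alone, 2 synthetases were higher, and 2 cytosolic ribosomal proteins and 1 stress gene lower. The other 11 lists, namely mitochondrial ribosomal proteins, proteasome, oxidative phosphorylation, DNA replication, ecdysone, JNK, matrix, signalling, developmental transcription factors, cell surface and remodellers, had medians of −0.14 to 0.09 and adjusted p of 0.07 to 0.616. The matrix list had a median of −0.03, a mean of 0.06 and a camera direction of lower. Over all 18 lists both tools called 0 members, with at most 5 members per list and direction at an unadjusted p under 0.05. Calls of 6 of these lists were lost without a library: mitosis without mock 1 (adjusted p = 0.104), cytosolic ribosomal proteins without mock 2 (0.139), stress without mock 2 (0.242), basal transcription without auxin 2 (0.16), immune without mock 1 (0.191) or auxin 2 (0.0662), and heat shock without mock 1 (0.0697), mock 2 (0.104) or auxin 2 (0.223). Transcription factors became called, lower, without auxin 1 (0.0343) or mock 2 (0.0442), and signalling and matrix genes without mock 2 (0.0249 and 0.0438).

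Snr1 is part of every Brahma complex, and its loss asks which genes need Brahma for continued transcription. Falls included members of the developmental, signalling, immune and cell surface lists, and rises members of the mitochondrial, proteasome and basal transcription lists, whose list calls were lost with an estimated correlation (adjusted p of 0.102 to 0.239). Of 90 developmental transcription factors measured 48 fell, with a list median of −1.29. So did 26 of 47 signalling targets (median −0.88), 24 of 46 hemocyte and extracellular matrix genes (−0.76) and 19 of 37 immune genes (−1.06). Rises took 24 of 73 mitochondrial ribosomal proteins (0.55), 22 of 75 oxidative phosphorylation genes (0.41) and 15 of 33 proteasome genes (0.40). DESeq2 called 14, 17 and 7 higher. In all, 1618 TSSs of 1417 genes fell by edgeR and 879 TSSs of 874 genes rose, with a median log2 size of 0.95.

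The largest falls included genes with almost no reads left after Snr1 depletion. Ca-alpha1T, a calcium channel gene (chromosome X, 6086381 to 6086530), went from 96 to 2 pooled counts, a ratio of 0.0192 with an exact interval of 0.00229 to 0.0711 (adjusted p = 2.74e-05). The serum response factor gene bs went from 87 to 3 counts, a ratio of 0.0317 (0.00641 to 0.0958). The pair-rule gene odd kept 1 of 25 counts (ratio 0.0368, 0.000896 to 0.225). Of the signalling targets, the FGF ligand gene ths had a ratio of 0.0484 (0.00969 to 0.149), and the Notch target E(spl)m7-HLH fell by 3.57 on the log2 scale (SE 0.60, adjusted p = 0.000235).

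Other falls came from the matrix, cell surface, immune, ecdysone, JNK, heat shock and stress lists, whose calls were lost with an estimated correlation (adjusted p of 0.102 to 0.555). The integrin gene scb fell from 191 ± 40.0 to 14.8 ± 4.46 CPM (−3.67 ± 0.38, adjusted p = 1.41e-06). The guidance cue gene NetA fell from 148 ± 12.6 to 16.9 ± 3.13 CPM (−3.13 ± 0.22, adjusted p = 3.92e-10), one of 26 of 62 cell surface genes to fall. Immune genes included PGRP-LB (−3.65 ± 0.54) and pirk (−2.11 ± 0.30), both negative regulators of the Imd pathway. Of 23 ecdysone genes 12 fell, among them those of the nuclear receptors Hr4, from 126 ± 9.3 to 23.9 ± 1.47 CPM (−2.40 ± 0.15, adjusted p = 6.51e-11), Hr38 (−1.97 ± 0.21) and Eip78C (−1.86 ± 0.15). Hr78 rose (0.71 ± 0.17). Of 23 JNK and apoptosis genes 10 fell, including the TNF gene egr (−1.28 ± 0.14). The 3 heat shock genes to fall, of 12, were Hsp23 (−3.21 ± 0.54, adjusted p = 0.000469), the cochaperone gene stv (−3.03 ± 0.31, adjusted p = 5.5e-07) and Hsp67Bc (−0.97 ± 0.31), whose call was lost without each of the 4 libraries (0.0604 to 0.129). Of 24 stress genes 8 fell, including crc, which encodes ATF4 (−2.03 ± 0.38), and Atf3 (−1.49 ± 0.34), and PEK rose (0.44 ± 0.16). Hr78 and PEK, like robo (0.50 ± 0.14) and PlexA (0.57 ± 0.18), the 2 cell surface genes that rose, are named after their values were seen, and each lost its call without at least 1 library.

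Among rises that held without each single library, the RNA polymerase II subunit gene Rpb4 (Polr2D) went from 15.8 ± 0.65 to 35.2 ± 3.01 CPM (1.16 ± 0.22, adjusted p = 0.000398). It was one of 11 of 44 basal transcription and splicing genes to rise (median 0.38). The respiratory chain genes CG9306 (ND-B22) and CG4169 (UQCR-C2) rose by 1.05 ± 0.22 and 0.74 ± 0.14, and the proteasome genes Rpt4 and Prosbeta3 by 0.80 ± 0.15 and 0.69 ± 0.13. O-fut1, a fucosyltransferase gene whose product modifies Notch (from 16.4 ± 2.06 to 38.3 ± 6.41 CPM, adjusted p = 0.000915), was among the 10 largest rises, of which 8 lost their call without at least 1 library. Among 44 remodellers 9 rose and 2 fell (median 0.29), tou (−2.02 ± 0.21) and Chd64, a gene of the calponin family (−0.57 ± 0.15, named after its values were seen). The synthetase genes that rose, 4 of 25 (median 0.36), were those for phenylalanine, tryptophan, glutamine and isoleucine (0.38 to 0.82), and the 3 cytosolic ribosomal protein genes, of 85 (median 0.18), were RpL12, RpL34b and RpL35A (0.41 to 0.52). Mitosis had 1 rise among 39 (glu, 0.48 ± 0.16; median 0.24). In DNA replication and S phase (41 genes, median 0.21) CycE (−0.82 ± 0.18, adjusted p = 0.00199), the cyclin E inhibitor gene dap (−0.60 ± 0.13) and E2f (−0.75 ± 0.18) fell and DNA-ligI, RfC38 and geminin rose (0.43 to 0.98), the last pair named after their values were seen. The calls of E2f, DNA-ligI, RfC38, geminin, glu, Chd64 and these synthetase and ribosomal protein genes were each lost without at least 1 library.

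By camera 9 lists lay below and 8 above the other genes in the Snr1 line. For developmental transcription factors, signalling, matrix, immune, cell surface (median −0.54), ecdysone (−0.60), JNK (−0.41), heat shock (−0.36) and stress genes (−0.28) the adjusted p = 1.09e-14, 1.17e-10, 2.61e-10, 1.56e-08, 1.28e-06, 1.8e-05, 0.00115, 0.0226 and 0.00823. With an estimated correlation they were adjusted p = 0.102, 0.102, 0.169, 0.169, 0.169, 0.102, 0.116, 0.555 and 0.479. Adjusted over the list alone, 59, 29, 27, 23, 30, 14, 11, 4 and 9 members fell. For mitochondrial ribosomal proteins, proteasome, oxidative phosphorylation, basal transcription, synthetases, remodellers, cytosolic ribosomal proteins and mitosis the adjusted p = 3.89e-08, 8.15e-07, 3.17e-07, 1.88e-05, 0.00133, 0.00769, 0.00769 and 0.0256. With an estimated correlation they were adjusted p = 0.239, 0.102, 0.121, 0.239, 0.134, 0.555, 0.653 and 0.676, and 36, 20, 23, 11, 2, 14, 0 and 0 members rose adjusted over the list alone. DNA replication was not called (adjusted p = 0.366), with 3 rises and 3 falls adjusted over the list alone. With members at 0 counts set to the floor, the medians were −1.28 for transcription factors, −0.91 for immune and −0.50 for cell surface genes, and unmoved for stress (−0.28) and ecdysone genes (−0.60).

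The fall was divided by promoter class. Of 3301 developmental TSSs 980 fell (29.7%) and 104 rose, with a median of −0.51 (−0.50 with 60 TSSs at the floor), and of 5976 housekeeping TSSs 572 fell (9.57%) and 672 rose, with a median of 0.19. The difference of the medians was −0.70 (camera adjusted p = 9.76e-17, and adjusted p = 0.00436 with an estimated correlation), and the odds ratio of falling was 3.99 (Fisher's exact test, p = 2.04e-130). In each library the median log2 CPM of developmental TSSs lay below that of housekeeping TSSs, by −0.88 and −0.86 in the mock and −1.69 and −1.64 in the auxin libraries. By promoter cluster, falls took 508 of 1454 TSSs with DPE and initiator motifs (cluster 2, 34.9%), 247 of 795 with a TATA box (cluster 1, 31.1%) and 225 of 1052 with an initiator alone (cluster 3, 21.4%). In cluster 4, of the housekeeping class with E-box and initiator motifs, 410 of 1492 TSSs fell (27.5%, median −0.27). Rises took 232 of 1462 TSSs in cluster 5 (Ohler1, 15.9%) and 255 of 1845 in cluster 7 (DRE and Ohler7, 13.8%), with cluster medians of 0.29 and 0.27. Cluster 8, with the TCT motif of ribosomal protein genes, had 32 of 213 TSSs lower (15%) and a median of 0.11.

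**Figure D1:**
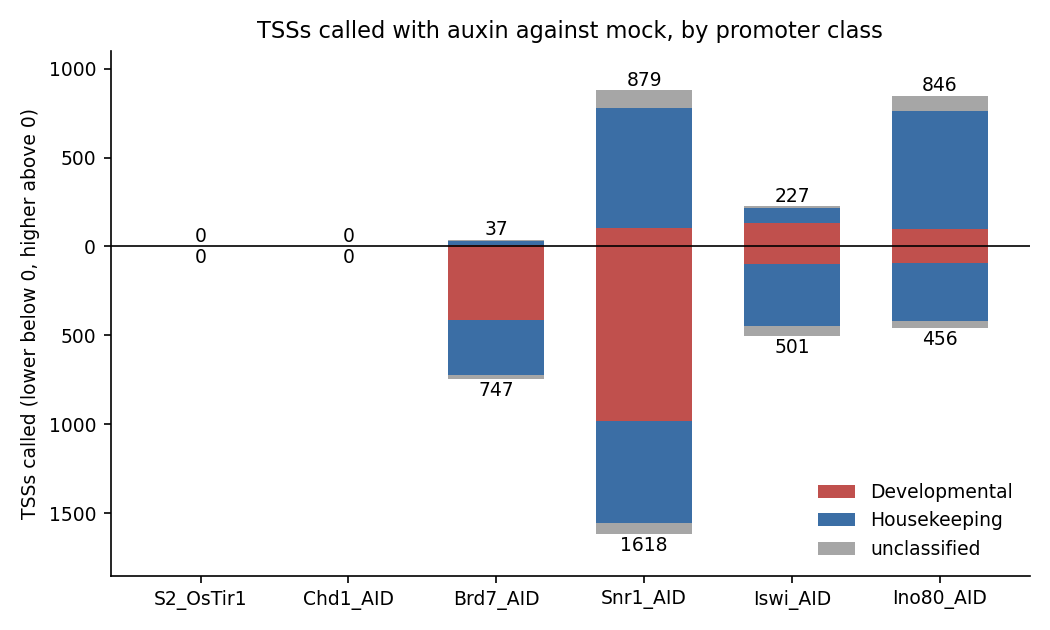
TSSs called higher (above 0) and lower (below 0) with auxin in each line, stacked by promoter class, at an adjusted p under 0.05 by edgeR. In the Snr1 line 980 developmental TSSs fell and 672 housekeeping TSSs rose; in the parental and Chd1 lines no TSS was called.

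Markers of other cell types were read in the same libraries. In the Snr1 line 4 of 5 epithelial, 4 of 8 ovarian somatic, 2 of 7 hemocyte, 1 of 3 neuronal and 1 of 5 muscle markers fell, with medians of −0.69, −0.75, −0.31, −0.80 and −1.58. Fas3, which counts as epithelial and ovarian, fell from 347 to 58.9 CPM (−2.56 ± 0.27, adjusted p = 3.58e-07), the hemocyte genes Pxn from 49.6 to 12.3 CPM (−2.04 ± 0.35, adjusted p = 0.000231) and srp from 374 to 159 CPM (−1.24 ± 0.19, adjusted p = 2.53e-05), and elav by 0.80. The falls of shg (−0.69) and br (−1.10) held without each library, while that of Tm1 (−0.49) was lost without any one of the 4 libraries (adjusted p of 0.085 to 0.102), that of sdt (−0.50) without auxin 1 (0.132) or mock 2 (0.12), both also with library size alone (0.143 and 0.0792), that of an ovarian marker with 0 counts left without auxin 1, mock 2 or auxin 2 (0.0554 to 0.16), that of Pxn in this line alone (0.121), and that of crb (−0.68) without mock 2 (0.0732). Of the 4 germ line markers and the 1 fat body marker measured, edgeR and DESeq2 called 0, with 0 at an unadjusted p under 0.05 (medians −0.35 and −0.65). In the Brd7 line 2 of 5 epithelial, 2 of 8 ovarian and 1 of 7 hemocyte markers fell, among them Fas3 (−3.39 ± 0.33, adjusted p = 3.98e-07) and mirr (−1.58 ± 0.29, adjusted p = 0.000562). Those of Pxn (−1.51) and crb (−0.65) were lost without at least 1 library. In the Ino80 line 1 of 7 hemocyte markers rose (crq, 1.11), and in the parental, Iswi and Chd1 lines edgeR and DESeq2 called 0 markers, with at most 2 per type at an unadjusted p under 0.05.

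Beyond the change of the parental line, 832 TSSs differed with auxin in the Snr1 line, 740 lower and 92 higher. Scaling moved the balance: of the calls 35.2% were higher with TMM, 23.6% with DESeq2 size factors (543 higher, 1757 lower) and 67.2% with library size alone (2780 higher, 1357 lower), which also moved the median of all TSSs from 0.04 to 0.28. Without auxin library 1, 907 TSSs fell and 219 rose, 476 differed beyond the parental change, with 541 falls and 23 rises in the developmental and 329 and 173 in the housekeeping class, 29 transcription factor, 14 matrix, 10 immune, 12 cell surface, 7 ecdysone and 5 JNK falls, and falls of 134, 279, 128 and 244 in clusters 1 to 4. With each library left out in turn, rises numbered 66 to 120 in cluster 5, 66 to 130 in cluster 7, 4 to 13 of mitochondrial ribosomal protein, 8 to 14 of oxidative phosphorylation, 4 to 8 of proteasome, 2 to 5 of basal transcription, 1 to 3 of remodeller and 1 to 2 of synthetase genes, and falls 4 to 8 of stress genes and 19 to 26 in cluster 8. In all, 244 TSSs rose and 1074 fell without mock 2, 393 rose without mock 1 and 473 without auxin 2, and the list calls of heat shock (auxin 1, adjusted p = 0.0501; mock 2, 0.0537), mitosis (auxin 1, 0.0585) and cytosolic ribosomal proteins (mock 1, 0.246; auxin 2, 0.17) were lost.

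Brd7, found in some but not all Brahma complexes, was depleted to ask which of these genes need it. Of developmental transcription factors 38 of 90 fell and of signalling targets 20 of 47, with medians of −1.24 (−1.20 with 2 members at the floor) and −0.65. Falls were also found for 11 of 62 cell surface (median −0.30), 10 of 46 matrix (−0.20), 6 of 23 JNK and apoptosis (−0.13) and 5 of 23 ecdysone genes (−0.36). These list calls were lost with an estimated correlation (adjusted p of 0.102 to 0.451). In all 747 TSSs of 704 genes fell and 37 TSSs of 37 genes rose, with a median size of 1.68. The transcription factor gene kn kept 1 of 77 pooled counts, a ratio of 0.0118 (0.000296 to 0.068; adjusted p = 6.72e-06).

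The planar polarity gene fj fell from 83.2 ± 4.16 to 3.86 ± 1.35 CPM (−4.40 ± 0.73, adjusted p = 0.00102), the perlecan gene trol from 315 ± 14.4 to 32.9 ± 1.42 CPM (−3.25 ± 0.27, adjusted p = 3.95e-08), and the integrin gene scb, with 174 ± 14.3 CPM in the mock libraries, by 3.28 on the log2 scale (SE 0.37, adjusted p = 1.18e-05). E(spl)m7-HLH fell by 3.75 (SE 0.53, adjusted p = 0.000104). The ecdysone genes were Hr38 (−1.38 ± 0.20, adjusted p = 3.21e-05), Eip74EF (−1.24 ± 0.17), Hr4 (−0.95 ± 0.13), Eip78C (−0.92 ± 0.14, named after its values were seen) and Eip63F-1 (−2.67 ± 0.72), whose call was lost without auxin 1 (0.246), mock 2 (0.153) or auxin 2 (0.0622). The heat shock genes to fall, 2 of 12, were stv (−2.12 ± 0.29, adjusted p = 5.19e-05) and Hsp67Bc (−1.46 ± 0.27), and PGRP-LB (−2.73 ± 0.44) was the 1 immune gene of 37. CG6415, 1 of 24 stress genes (−1.63), and tou, 1 of 44 remodellers (−0.80 ± 0.20), lost their calls without at least 1 library. The 3 proteasome genes of 33 that rose, Rpn3, Rpt3 and Prosbeta3 (0.45 to 0.52), and each of the 10 largest rises (0.56 to 1.34) did too.

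Camera placed 8 lists below the others in the Brd7 line. For developmental transcription factors, signalling, cell surface, matrix, ecdysone, JNK, heat shock (median −0.25) and immune genes (−0.15) the adjusted p = 9.2e-21, 5.4e-13, 2.05e-06, 3.73e-05, 3.75e-05, 0.0117, 0.00752 and 0.0314. They were adjusted p = 0.102, 0.102, 0.169, 0.451, 0.102, 0.208, 0.515 and 0.634 with an estimated correlation, and 48, 22, 15, 10, 10, 8, 3 and 1 members fell adjusted over the list alone. The 6 lists above the others were proteasome (0.34), mitochondrial ribosomal proteins (0.27), oxidative phosphorylation (0.22), basal transcription (0.23), synthetases (0.29) and remodellers (0.19), with adjusted p = 8.23e-08, 1.03e-05, 5.55e-06, 0.000161, 0.000216 and 0.0102. With an estimated correlation the values were adjusted p = 0.102, 0.419, 0.169, 0.338, 0.102 and 0.559. Adjusted over the list alone, 6 proteasome genes rose and 1 remodeller fell. Among mitochondrial ribosomal, oxidative phosphorylation, basal transcription and synthetase genes edgeR and DESeq2 called 0 members, with 6, 15, 7 and 5 higher at an unadjusted p under 0.05. Stress genes (−0.04, adjusted p = 0.631; 1 member lower adjusted over the list alone), cytosolic ribosomal proteins (0.04, 0.388; 0.041 with library size alone), DNA replication (0.15, 0.261) and mitosis (0.05, 0.538) were not called, and in the last 3 both tools called 0 members, with 2, in DNA replication, at an unadjusted p under 0.05. At the floor the medians of the immune and matrix lists were −0.14 and −0.19.

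By class 414 developmental TSSs fell (12.5%) and 7 rose (median −0.17, −0.16 with 48 TSSs at the floor), and 306 housekeeping TSSs fell (5.12%) and 25 rose (median 0.11). The class difference was −0.28 (camera adjusted p = 2.06e-10, and adjusted p = 0.015 with an estimated correlation; odds ratio of falling 2.66, Fisher's exact test, p = 1.37e-35). Per library it was −0.72 and −0.76 in the mock and −1.09 and −1.23 in the auxin libraries. Cluster 4 had the highest share of falls, 244 of 1492 TSSs (16.4%), then cluster 2 with 218 (15%) and cluster 1 with 112 (14.1%), against 14 in cluster 5 and 21 in cluster 7. Beyond the parental change 275 TSSs differed, 268 lower and 7 higher. Without auxin library 1, 362 TSSs fell, with 191 in the developmental class, 154 in the housekeeping class, 132 in cluster 4, 49 in cluster 1, 100 in cluster 2, 3 in cluster 5, 8 in cluster 7, 20 transcription factors, 12 signalling, 7 cell surface, 6 matrix and 2 JNK genes, and 126 differed beyond the parental change (151 to 160 without Brd7 mock 2 or auxin 2, or parental mock 2 or auxin 2). Falls numbered 494, 459 and 393 without mock 1, mock 2 and auxin 2 and rises 0 to 9 with each library left out in turn, whereas a fit of this line alone gave 1526 falls and 639 rises, and the immune call was lost without mock 2 (adjusted p = 0.138) or auxin 2 (0.0737) and with library size alone (0.0588), which moved the median of all TSSs from 0.05 to 0.16.

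Whether the losses of Snr1 and Brd7 act on different genes was tested as a difference of effects. Of the 747 TSSs lower in the Brd7 line 641 (85.8%) were also lower in the Snr1 line, where independent lists would share 115.9 (Fisher's exact test, adjusted p = 2.4e-299 over 24 overlaps). Across TSSs, which are not independent replicates, the effects correlated with r of 0.70 and rho of 0.63. The effects differed at 186 TSSs, 181 lower in the Snr1 line, 110 of them developmental and 65 housekeeping. The hemocyte receptor gene NimC4 changed by −3.29 with Snr1 and 0.91 with Brd7 depletion, a difference of −4.19 ± 0.57 (adjusted p = 7.32e-05). In the other direction 5 TSSs were called, among them Notum (−1.20 against −2.71, adjusted p = 0.043), whose call was lost without at least 1 library. The count of 186 became 108 without Snr1 auxin 1, 110 without Brd7 mock 1, 112 without Brd7 auxin 2 and 290 without Snr1 auxin 2.

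**Figure D2:**
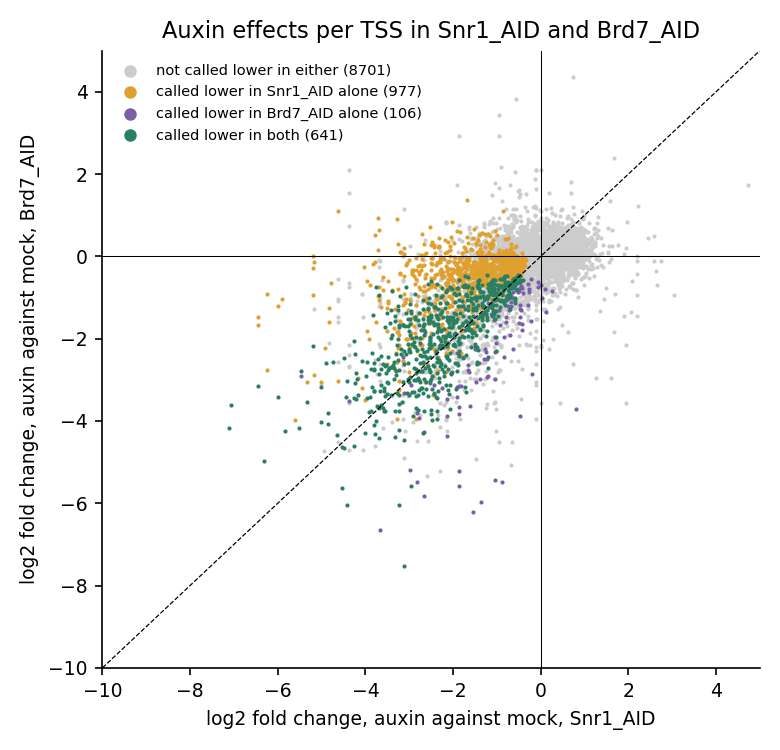
Log2 fold change of auxin over mock in the Snr1 (x axis) and Brd7 lines (y axis), 1 point per TSS. Colour gives the lines in which it was called lower, and the dashed line marks equal changes. Of 10425 TSSs 641 were called lower in both, 977 only in Snr1 and 106 only in Brd7, but effects differed at 186.

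Iswi is the ATPase of several remodellers that space nucleosomes, and its loss asks which genes depend on them. Ribosomal protein and mitosis genes were among those that fell, and a few developmental transcription factors among those that rose. IntS3, a subunit gene of the Integrator complex, fell from 146 ± 8.61 to 40.5 ± 5.32 CPM (−1.85 ± 0.16, adjusted p = 1.15e-07). Ucrh (UQCR-11; scaffold 3LHet) fell from 75.2 ± 13.1 to 19.5 ± 3.01 CPM (−1.95 ± 0.22, adjusted p = 4.72e-06) and Dbp80 changed by −1.64 ± 0.18. Of 85 cytosolic ribosomal protein genes 12 fell (median −0.26), RpL21 by 0.96 on the log2 scale, from 275 ± 1.39 to 141 ± 5.42 CPM (SE 0.14, adjusted p = 0.000118). In all 501 TSSs of 499 genes fell and 227 TSSs of 220 genes rose, with a median size of 0.83.

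Other falls were Grip84 (−2.07 ± 0.32) and Alg-2 (−1.62 ± 0.17). Of 39 mitosis genes 6 fell (median −0.26), among them the cyclin gene CycB3, from 208 ± 0.11 to 111 ± 4.72 CPM (−0.90 ± 0.13, adjusted p = 0.000126), and the midzone gene feo (−1.16 ± 0.18). Rises were led by Aldh-III, from 6.89 ± 5.79 to 67.1 ± 20.9 CPM (3.25 ± 0.55, adjusted p = 0.00103), and the homeobox gene Vsx1, from 1.85 ± 0.02 to 16.3 ± 2.93 CPM (3.12 ± 0.62, adjusted p = 0.00273). Of 90 developmental transcription factors 4 rose (median 0.29), en, from 39.9 ± 17.2 to 132 ± 42.9 CPM (1.72 ± 0.29, adjusted p = 0.000677), and D, Doc1 and ems (1.55 to 2.51), and lab fell (−1.10 ± 0.32, named after its values were seen). Of these en kept its call without each library, and the other 4 did not.

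Camera placed cytosolic ribosomal proteins, mitosis and synthetase genes (median −0.19) below the other genes, with adjusted p = 2.43e-09, 0.0014 and 0.00769, and adjusted p = 0.369, 0.6 and 0.208 with an estimated correlation. Adjusted over the list alone 21, 10 and 3 members fell, and over all TSSs the synthetases that fell were those for valine and methionine, 2 of 25, both calls being lost without auxin 1. Above the other genes lay developmental transcription factors, immune (0.28), matrix (0.22) and ecdysone genes (0.20), with adjusted p = 1.56e-08, 9.77e-05, 0.000216 and 0.00973, and adjusted p = 0.221, 0.419, 0.515 and 0.302 with an estimated correlation. Adjusted over the list alone 4, 1, 2 and 2 members rose and 1, 0, 0 and 1 fell. The called members were PGRP-SA (immune), NimC4 and BM-40-SPARC (matrix) and ImpE3 (ecdysone), all higher and each lost without at least 1 library, and Eip55E (ecdysone, −1.14 ± 0.18, adjusted p = 0.00031), a gene of cysteine synthesis in newer annotation (Cth).

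Not called were oxidative phosphorylation (6 of 75 lower, median −0.13, adjusted p = 0.07), remodellers (median −0.11, adjusted p = 0.0633) and DNA replication (−0.13, adjusted p = 0.366), with 6, 6 and 4 members lower and 0, 1 and 1 higher adjusted over the list alone. The remodellers that fell were pho (−1.14 ± 0.18, adjusted p = 0.00031), CG11970, Chd3, Chrac-16 and Nurf-38 (the last named after its values were seen), with Iswi itself higher. Of the genes named in this paragraph, all but pho and bsk lost their calls without at least 1 library. In DNA replication dpa and PCNA fell and CycE rose. Cell surface (Nrg, tsr, kst and beta-Spec lower, median 0.04, adjusted p = 0.917), signalling (Egfr, fz3 and Dl lower, btl higher, 0.12, 0.152), stress (CG10924 higher, CG18619 lower, 0.13, 0.435) and JNK genes (bsk, which encodes the JNK kinase, −1.10 ± 0.19, and Iap2 lower, p53 higher, 0.09, 0.768) gave the same counts adjusted over the list alone. Mitochondrial ribosomal proteins (mRpS5 lower, −0.03, 0.726), proteasome (Rpt6 lower, −0.07, 0.765) and basal transcription (Xpd and TfIIA-S lower, −0.04, 0.526) had 0 members called adjusted over the list alone. Of 12 heat shock genes edgeR and DESeq2 called 0, with 0 at an unadjusted p under 0.05 (0.18, 0.358). Median, mean and camera direction differed in sign for mitochondrial ribosomal proteins (mean 0.00, higher), JNK (mean −0.01, higher) and cell surface genes (mean −0.02, lower). Without single libraries DNA replication was called in opposite directions, lower without mock 1 (adjusted p = 0.00017) or auxin 2 (0.000171) and higher without auxin 1 (0.0196) or mock 2 (0.0441). Without mock 1 or auxin 2 oxidative phosphorylation (0.0236 and 0.00821) and remodellers (0.00506 and 0.000992) were called lower, as with library size alone (0.0485 for both), and heat shock (0.0131 and 0.00912) and signalling genes (0.0131 and 0.0103) higher, with basal transcription lower without auxin 2 (0.0372) and mitochondrial ribosomal proteins higher without auxin 1 (0.00854).

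By class the median change in the Iswi line had the opposite sign to that in the Snr1 and Brd7 lines. Of developmental TSSs 132 rose and 96 fell (median 0.20), and of housekeeping TSSs 83 rose and 351 fell (median −0.05). The class difference was 0.25 (camera adjusted p = 1.82e-07, and adjusted p = 0.0345 with an estimated correlation). Per library the developmental median lay at −0.46 and −0.87 from the housekeeping median in the mock and −0.19 and −0.47 in the auxin libraries. It rose within both numbers, which may not pair libraries, but the mock libraries differed by more than 0.25. Cluster 6 had 90 of 964 TSSs lower (9.34%), cluster 8 16 (7.51%), cluster 7 121 (6.56%) and cluster 5 79. Clusters 2 and 4 had 67 (4.61%) and 59 (3.95%) higher. The effect correlated negatively with those of Snr1 (r −0.35, rho −0.37) and Brd7 (r −0.29, rho −0.28), and 97 TSSs lower without Snr1 were higher without Iswi, against 35.2 for independent lists (adjusted p = 1.56e-22).

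**Figure D3:**
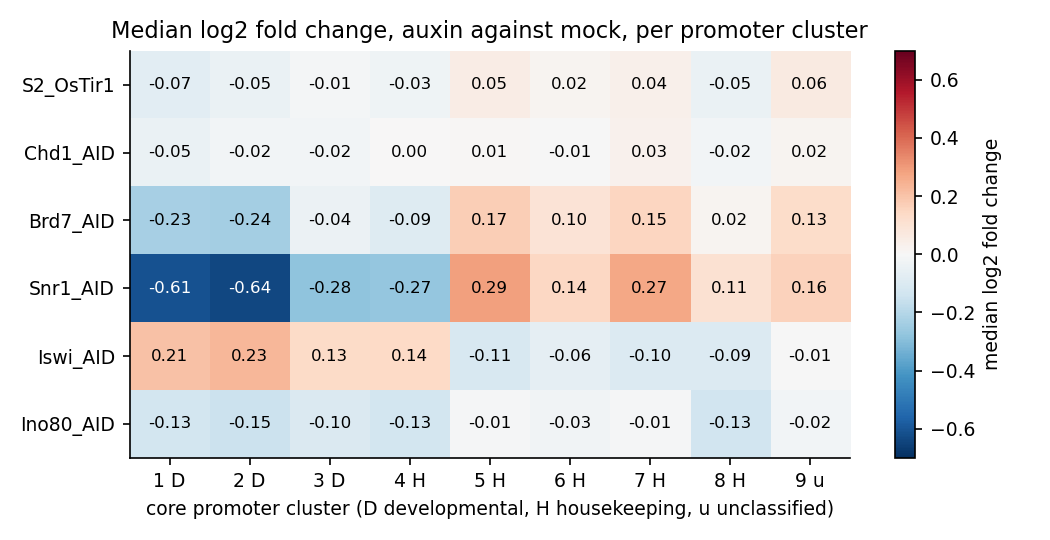
Median log2 fold change of auxin over mock for the TSSs of each promoter cluster (1 to 9) in each line; colour gives the median. Clusters 1 to 4 were lowest in the Snr1 line (−0.64 to −0.27) and above 0 in the Iswi line.

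Beyond the parental change 113 TSSs differed in the Iswi line, 99 lower and 14 higher. Without auxin library 1, 43 TSSs rose and 185 fell, the class difference was 0.09 (adjusted p = 0.0359), 22 developmental TSSs rose, 41 developmental and 120 housekeeping TSSs, 31, 45, 29 and 6 TSSs of clusters 5 to 8, 2 ribosomal protein and 2 mitosis genes fell, and the list calls of mitosis (0.566), ecdysone (0.11), synthetases (0.0626), immune (0.149) and matrix genes (0.0554) were lost. Without mock library 2, 41 TSSs rose, 21 of them developmental and 18 housekeeping, and 244 fell, 160 of them housekeeping and 39, 53, 38 and 11 in clusters 5 to 8, with 6 ribosomal protein and 2 mitosis genes, the class difference was 0.11 (adjusted p = 0.029), and the calls of mitosis (0.366) and ecdysone (0.118) were lost. Rises in clusters 2 and 4 became 13 and 14 without auxin 1 and 13 each without mock 2. With each library left out in turn, rises ranged over 1 to 12 of transcription factors and 0 to 4 of immune genes, and falls over 1 to 6 of oxidative phosphorylation, 2 to 11 of mitosis, 1 to 7 of remodeller and 0 to 5 of DNA replication genes. A fit of this line alone called 12 TSSs higher and 21 lower. The 113 became 41 without parental auxin 2, 45, 52 and 56 without parental mock 1, auxin 1 and mock 2, 50 without Iswi auxin 1, 63 without Iswi mock 2, 236 without Iswi mock 1 and 187 without Iswi auxin 2.

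Ino80 is the ATPase of a remodeller that acts on nucleosomes next to promoters, and its loss asks which TSSs depend on it. Here 846 TSSs of 843 genes rose and 456 TSSs of 448 genes fell, with 3 libraries per group and a median size of 0.77. The splicing factor gene Slu7 rose from 20.9 ± 3.64 to 139 ± 11.3 CPM (2.74 ± 0.18, adjusted p = 4.35e-10) and the palmitoyltransferase gene Dnz1 by 2.51 on the log2 scale (SE 0.18). The transcription termination factor gene lds fell from 31.3 ± 1.59 to 7.23 ± 1.45 CPM (−2.17 ± 0.23, adjusted p = 3.31e-07) and the core spliceosome gene SmB from 67.7 ± 5.45 to 16.7 ± 7.88 CPM (−1.91 ± 0.19). With the numbered replicate as a block, 1225 TSSs rose and 1392 fell.

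The largest rise was lectin-24Db (3.23 ± 0.51), and the Notch effector gene Su(H) rose from 79.5 ± 30.3 to 325 ± 26.9 CPM. Of 73 mitochondrial ribosomal protein genes 14 rose, including mRpL27 (1.75 ± 0.23), and mRpS18B and mRpS31 fell (named after their values were seen). Of 75 oxidative phosphorylation genes 14 rose, among them ND23 (1.57 ± 0.20) and CG14482 (UQCR-6.4) (1.29 ± 0.13). The 4 that fell, Ucrh (−1.08 ± 0.21), ATPsynG, CG9140 and CG4769, are named after their values were seen. Basal transcription and splicing genes went both ways, 8 higher and 10 lower of 44, with Prp31 at 1.11 ± 0.19 and the TATA-binding protein gene Tbp at −0.90 ± 0.14. Proteasome genes had 6 rises of 33, with Prosalpha3 (0.93 ± 0.14), and Rpn11 as the 1 fall (−1.35 ± 0.15, adjusted p = 9.39e-07). Of 39 mitosis genes 7 rose, with Kmn1 at 1.56 ± 0.19, and pim and Bub3 fell (named after their values were seen). The calls of pim, Bub3, mRpS18B, CG9140 and CG4769 were each lost without at least 1 library.

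Camera placed mitochondrial ribosomal proteins (median 0.10, adjusted p = 0.0112) and oxidative phosphorylation (0.11, 0.0139) above the other genes, with adjusted p = 0.614 and 0.535 with an estimated correlation; 16 and 18 members rose and 2 and 6 fell adjusted over the list alone. Below lay immune genes (−0.20, adjusted p = 0.00484), cytosolic ribosomal proteins (−0.13, 0.0121), developmental transcription factors (−0.23, 0.0139), cell surface (−0.16, 0.0139) and matrix genes (−0.20, 0.0421), with adjusted p = 0.553, 0.662, 0.631, 0.551 and 0.659 with an estimated correlation. Their members lower were 0, 3, 1, 5 and 1, and 0, 2, 1, 5 and 1 adjusted over the list alone, with 1 cytosolic ribosomal protein, 1 cell surface and 2 matrix genes higher in both. Among immune genes edgeR called 0, with 6 lower at an unadjusted p under 0.05, and DESeq2 called 1. RpL28 rose (0.63 ± 0.11) and RpS18 (−0.76 ± 0.14), RpL5 and RpL31 fell; sd fell (−0.68 ± 0.15); PlexB (−1.22 ± 0.20), PlexA (−1.11 ± 0.18), Lar, NetB and robo fell, the last pair named after their values were seen, and Nrg rose. The engulfment receptor gene crq, from 100 ± 9.89 to 218 ± 44.0 CPM (1.11 ± 0.17), and the integrin gene mys (0.65 ± 0.10) rose and Mmp2 fell. The calls of RpL5, RpL31, robo, Nrg and Mmp2 were each lost without at least 1 library. With the block the members lower were 17 for cytosolic ribosomal proteins, 19 for transcription factors, 20 for cell surface, 16 for matrix, 14 for immune and 8 for oxidative phosphorylation, with 5 cytosolic ribosomal protein, 2 cell surface and 1 transcription factor genes higher.

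The remaining Ino80 lists were not called. They were basal transcription (−0.20, adjusted p = 0.127; 8 and 12 members adjusted over the list alone), mitosis (0.10, 0.169; 10 and 3), proteasome (0.11, 0.103; 6 and 1) and remodellers (−0.10, 0.172; 3 and 5). The remodellers higher were rept (0.94 ± 0.18), Chd3 and brm, and those lower lds, CG11970 (−1.05 ± 0.17), Bap170 (−0.84 ± 0.14), Chd1 and kis, of which Chd3, brm, Chd1 and kis are named after their values were seen. Synthetases (those for isoleucine, −0.76 ± 0.11, serine and alanine lower; −0.03, 0.542), DNA replication (Mcm6 and Gnf1 higher, RfC38 lower; 0.06, 0.526), JNK (Iap2, 0.94 ± 0.14, and hep higher; median −0.06, mean −0.01 and camera direction higher, 0.912), signalling (Axn higher; −0.10, 0.169, and called lower with the block, adjusted p = 0.041) and stress genes (Hsc70-3 lower; −0.09, 0.167) gave the same counts adjusted over the list alone. Ecdysone genes (usp higher and Eip63E, Hr78 and Hr4 lower; −0.07, 0.169) had 4 lower adjusted over the list alone. The calls of Mcm6, Hsc70-3, usp, Hr78, Hr4 and the serine and alanine synthetase genes were each lost without at least 1 library. Of 12 heat shock genes both tools called 0, with 1 at an unadjusted p under 0.05 (−0.30, 0.18). With the block 9 DNA replication, 12 mitosis and 6 remodeller genes were higher and 3, 5 and 8 lower, 8 signalling, 6 heat shock, 5 ecdysone, 5 JNK, 5 stress and 4 mitochondrial ribosomal protein genes lower, and 2 synthetase, 1 heat shock and 1 stress genes higher. With each library left out in turn, falls ranged over 2 to 7 of cytosolic ribosomal protein, 1 to 3 of transcription factor, 5 to 8 of cell surface, 0 to 2 of matrix and of immune, 0 to 3 of mitosis, 1 to 4 of ecdysone and 2 to 5 of oxidative phosphorylation genes, and rises over 5 to 7 of basal transcription genes.

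By class 667 housekeeping TSSs rose (11.2%) and 325 fell (5.44%), and 97 developmental TSSs rose and 94 fell. The class difference was −0.08 (camera adjusted p = 0.0273, and adjusted p = 0.36 with an estimated correlation), with per-library values of −0.44, −0.66 and −0.52 in the mock and −0.60, −0.72 and −0.72 in the auxin libraries. Rises were most frequent in clusters 7 (275 of 1845, 14.9%) and 5 (215 of 1462, 14.7%). With the block 754 housekeeping and 547 developmental TSSs fell and 164 developmental TSSs rose, and falls in clusters 1 to 8 went from 12, 45, 37, 86, 76, 34, 121 and 8 to 123, 279, 145, 265, 155, 70, 228 and 36. Beyond the parental change 343 TSSs differed, 245 higher and 98 lower, and 847 with the block. Of the calls 65% were higher, 77.9% with library size alone (903 and 256) and 46.8% with the block. The class call was lost without mock 1 (adjusted p = 0.083), auxin 2 (0.0503), mock 3 (0.0624) or auxin 3 (0.0746); the calls of matrix (mock 1, 0.128; auxin 1, 0.0956), transcription factor (mock 1, 0.0976; auxin 3, 0.107), cytosolic ribosomal protein (mock 2, 0.122) and oxidative phosphorylation lists (auxin 3, 0.0596) were lost in the same way, developmental falls became 58 and those in clusters 1 to 4 6, 29, 23 and 51 without mock 3, those in clusters 5 to 7 49, 21 and 77 without auxin 1, and the 343 became 185 to 202 without each of the 4 parental libraries.

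The Snr1 and Ino80 effects were compared directly, as the pair with the most calls. They differed at 1959 TSSs, 1216 lower and 743 higher in the Snr1 line (3846 with the block, 1163 without Snr1 auxin 1). Developmental TSSs made up 597 of those lower and 95 of those higher, and housekeeping TSSs 543 and 570. The gene dnd changed by −3.18 with Snr1 and by 1.96 with Ino80 depletion, a difference of −5.13 ± 0.74 (adjusted p = 3.42e-05). TSSs that rose without Snr1 were found more often than in independent lists both among the rises without Ino80 (136 against 71.3, odds ratio 2.28) and among the falls (73 against 38.4, odds ratio 2.17), shared falls numbered 69 against 70.8, and 10 TSSs fell without Snr1 and rose without Ino80, against 131.3 (adjusted p = 1.76e-48). Across TSSs r was 0.17 and rho 0.199. For pairs with the parental or Chd1 line, in which no TSS was called, r lay within 0.01 and 0.09 and rho within −0.052 and 0.195. No mock libraries were shared between lines.

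**Figure D4:**
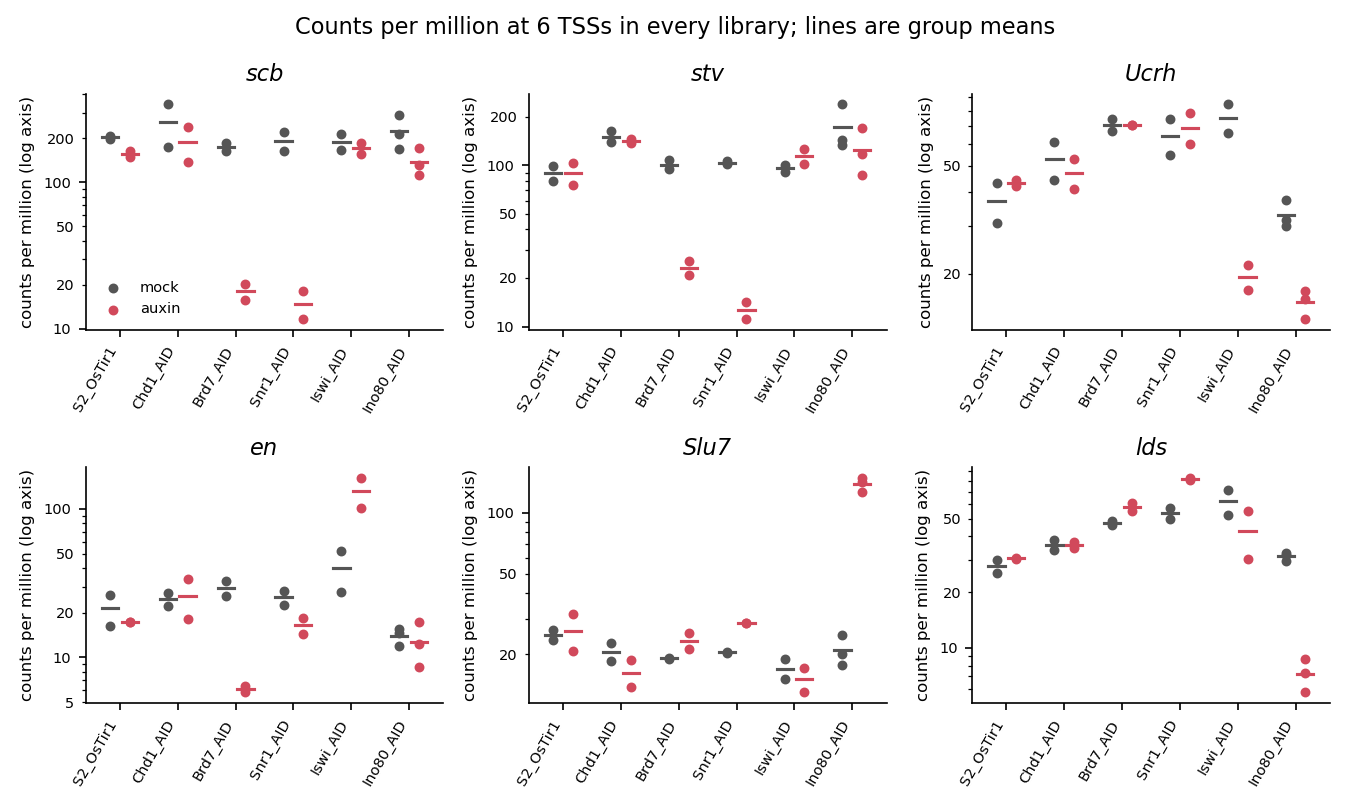
CPM per library on a log axis for the TSSs of scb, stv, Ucrh, en, Slu7 and lds in the 6 lines, mock in grey and auxin in red, with bars at the group means (2 libraries per group, 3 for Ino80). For example, scb fell from 191 to 14.8 CPM in the Snr1 line and lds from 31.3 to 7.23 CPM in the Ino80 line.

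Chd1 is a remodeller that travels with elongating polymerase, and its depletion asks whether ongoing transcription at TSSs needs it. Elongation beyond the 150 bp windows was not measured. EdgeR and DESeq2 called 0 of 10425 TSSs, and 0 differed beyond the parental change. At an unadjusted p under 0.05 were 105 (1%) and 240 (2.3%). The block called 13 higher and 5 lower. Simulations recovered 83.3% of 4-fold and 49.3% of 2-fold changes here, if lines vary alike. Chd1 replicates differed by 10.61 and 12.58 times counting noise (r 0.973). The class difference was −0.04 (camera adjusted p = 0.0631), and that of the parental line −0.06 (adjusted p = 0.0631). It became −0.11 (adjusted p = 0.00449) without auxin 1, −0.08 (0.0106) without mock 2 and 0.02 (0.332) without auxin 2.

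Medians of the Chd1 lists lay within −0.15 and 0.06. Mitosis (median −0.11), cell surface (−0.04), heat shock (−0.15), cytosolic ribosomal proteins (−0.03), DNA replication (−0.05), signalling (−0.08) and stress genes (−0.06) were below the other genes by camera, with adjusted p = 6.95e-05, 0.00505, 0.0122, 0.0139, 0.0189, 0.0195 and 0.0286. With an estimated correlation the values were adjusted p = 0.551, 0.515, 0.535, 0.673, 0.676, 0.593 and 0.551. Mitochondrial ribosomal proteins (0.06) and proteasome genes (0.04) were above, with adjusted p = 0.0309 for each, and adjusted p = 0.653 and 0.535 with an estimated correlation. Synthetases, oxidative phosphorylation, basal transcription, ecdysone, immune, JNK, matrix, transcription factor and remodeller lists had medians of −0.04 to 0.05 and adjusted p of 0.114 to 0.931. Median and mean differed in sign for ecdysone (−0.04 and 0.00), immune (−0.01 and 0.04) and matrix genes (−0.02 and 0.03), all with a camera direction of lower, and remodellers had a median and mean of 0.01 and the same camera direction. Over the 18 lists both tools called 0 members and 0 were called adjusted over the list alone, with at most 1 per list at an unadjusted p under 0.05. Mitosis kept its call, and each of the other 8 calls was lost without at least 1 library, with adjusted p of up to 0.869. Matrix genes were called higher without mock 1 (0.0336) or auxin 2 (0.00091) and lower without auxin 1 (0.000616) or mock 2 (0.00914). Transcription factors (0.0296 and 0.0173) and immune genes (0.0291 and 0.0369) were called lower without auxin 1 or mock 2, and JNK genes without auxin 1 (0.0419).

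The lines also differed before auxin. Against the parental mock libraries, 3273 TSSs differed in the mock Snr1 line (1816 higher, 1457 lower), 3299 in the Iswi line (1820, 1479), 4174 in the Ino80 line (2098, 2076), 3639 in the Chd1 line (1903, 1736) and 3338 in the Brd7 line (1744, 1594). Without parental mock 1 the counts of the Iswi and Brd7 lines were 2144 and 2188, and without parental mock 2 that of the Iswi line was 2187. The effects of auxin given for each line are relative to its own mock libraries.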

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

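The tests of depth, of one common factor, of the scaling of the Iswi class difference and of the replicate pairs in the Ino80 line were chosen only after the results they bear on had been seen, as was the use of Ino80 replicates 2 and 3 alone.

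The effect of auxin differed between lines by tests of the difference itself. Against the parental effect it differed at 832 TSSs in the Snr1, 275 in the Brd7, 343 in the Ino80 and 113 in the Iswi line. Between tagged lines it differed at 186 TSSs for Snr1 against Brd7 and at 1959 for Snr1 against Ino80. With 1 library left out the lowest of these counts were 476, 126, 185, 41, 108 and 1163 in the same order, without Snr1 auxin 1, Brd7 auxin 1, parental auxin 2, parental auxin 2, Snr1 auxin 1 and Snr1 auxin 1.

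In the Iswi line developmental TSSs moved up against housekeeping TSSs, with a class difference of 0.246 (0.09 without auxin 1 and 0.11 without mock 2). One factor per library moves both classes alike, so the value with library size alone (0.244) does not test the scaling. Variation between cultures along the same axis stays open, as pairing is unknown. The effect correlated across TSSs with the difference of the mock libraries at r of 0.274, the median difference per TSS between replicates (1 minus 2) was higher in the developmental class by 0.278 (mock) and 0.314 (auxin), and 0.136 was left after both replicate differences were removed. The loss of Iswi, which the design names, likewise stays open, as untested.

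Of the 186 TSSs at which the Snr1 and Brd7 effects differed, 181 were lower in the Snr1 line. A difference in depth is argued against, since the Brd7 libraries held 1.08 times the mean total count of the Snr1 libraries. A uniformly smaller effect of Brd7 depletion was tested with the Snr1 effects multiplied by 0.502, the median ratio over the TSSs that fell. Still 58 TSSs differed, 39 lower and 19 higher in the Brd7 line, which argues against a common factor for these 58. For the other TSSs it stays open, as 58 lies between the bounds of 20 (for) and 100 (against). A different need of genes for Snr1 and for Brd7, which the design names, and a different completeness of depletion stay open, as untested.

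In the Ino80 line 65% of the calls were higher. The share moved with the scaling (59.9% with DESeq2 size factors, 77.9% with library size alone), which stays open without spike-in scaling. The values argue against replicate 1 alone (70.7% with replicates 2 and 3). With the pairs as a block 46.8% were higher, as falls went from 456 to 1392 and rises from 846 to 1225. Whether pair differences account for the excess of rises stays open. Of the 10 splits of the 6 libraries 1, the real one, gave 1302 calls and the highest other gave 79, and 10 splits are too few for a share under 0.05; the 3 other splits that part all 3 pairs gave 0 calls and the 6 that keep pairs together gave 0 to 79. An effect of the loss of Ino80, which the design names, stays open as untested.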

How the results depend on the processing

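Replicates 2 and 3 of the Ino80 line alone and the class and list tests without a filter were chosen only after the results had been seen. Counts summed per gene left 24 of 24 counts of calls within 1.5 times the value given, and a stricter filter on low counts 30 of 30. The class differences of the Snr1, Brd7 and Iswi lines kept their direction and stayed called under every alternative run for them. With a library left out, the one that remains in its group was assumed to vary like the other groups. On data simulated at these depths and numbers of libraries 34.3% to 59.7% of 2-fold and 7.5% to 17.9% of 1.5-fold changes were recovered per line, so that many such changes would not be detected, and depth alone was not varied. Scaling to spike-in totals was planned and not run. For all changes given here the cause was not tested, except that a fit of a line alone and the leaving out of libraries use fewer samples.

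With an estimated correlation 0 lists were called in each of the 6 lines, and the Ino80 class difference of −0.081 had an adjusted p of 0.36. DESeq2 size factors gave 543 TSSs higher in the Snr1 line. Library size alone gave 2780 higher in the Snr1 line, 256 lower in the Ino80 line and 97 higher in the Brd7 line, and called the class differences of the parental (−0.062, adjusted p = 0.0345) and Chd1 lines (−0.038, 0.0401). The DESeq2 Wald test called 3 TSSs lower in the parental line and 425 higher in the Snr1 line. Without a filter 1 TSS was higher and 2 lower in the parental line, 577 higher in the Snr1, 415 in the Iswi, 2 in the Chd1 and 16 in the Brd7 line, 1256 and 672 differed beyond the parental change in the Snr1 and Brd7 lines, and 431 between Snr1 and Brd7. In that setting the class difference was 0 in the parental line (adjusted p = 0.0368) and −0.053 in the Ino80 line (0.125), and 4 lists were called in the Chd1 line. Fits of one line alone called 2 TSSs higher and 17 lower in the parental line, 518 higher in the Snr1 line, 12 higher and 21 lower in the Iswi line, 198 lower in the Ino80 line, and 639 higher and 1526 lower in the Brd7 line. Replicates 2 and 3 alone gave 292 TSSs lower in the Ino80 line. At TSSs with a mean of at least 2 CPM the correlations of effects were −0.377 for Snr1 and Iswi, 0.74 for Snr1 and Brd7, −0.098 for Iswi and Ino80, −0.306 for Iswi and Brd7, and 0.084 for Ino80 and Chd1.

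In the lines with 2 pairs the samples share only a number, and same-numbered deviations correlated at 0.537 (Snr1), 0.608 (Iswi), 0.682 (Chd1), 0.174 (Brd7) and −0.002 (parental). With the replicate block the Snr1 gene became called in its line (adjusted p = 0.00286), and 2466 TSSs were higher and 2543 lower in the Snr1 line, 1498 and 1457 in the Iswi line, 800 and 1491 in the Brd7 line, 13 and 5 in the Chd1 line and 5 and 23 in the parental line, and the parental class difference was −0.065 (adjusted p = 0.0456). In the Ino80 line, taken as paired, 1392 were lower, the signalling list became called (adjusted p = 0.041), and the block changed no other class or list call (class difference −0.098). Beyond the parental change the block gave 2156 TSSs for Snr1, 1362 for Iswi, 847 for Ino80, 2 for Chd1 and 1065 for Brd7, with 919 for Snr1 against Brd7 and 3846 for Snr1 against Ino80.

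With each library left out in turn, the TSSs higher ranged over 219 to 473 in the Snr1, 41 to 244 in the Iswi and 0 to 9 in the Brd7 line, and those lower over 907 to 1408, 185 to 463 and 362 to 494. The Ino80 line had 656 to 778 higher and 321 to 503 lower. Beyond the parental change the counts were 476 to 800 for Snr1, 41 to 236 for Iswi, 185 to 371 for Ino80 and 126 to 200 for Brd7, and the direct comparisons gave 108 to 290 for Snr1 against Brd7 and 1163 to 2145 for Snr1 against Ino80. Mock lines differed from the parental mock at 2144 to 3375 TSSs for Iswi and 2188 to 3267 for Brd7. Lists called numbered 3 to 12 in the Chd1, 4 to 13 in the Iswi and 4 to 8 in the parental line. The class difference ranged from −0.132 to −0.043 in the Ino80 line, from 0.09 to 0.435 in the Iswi line and from −0.113 to 0.019 in the Chd1 line, where without auxin 2 its sign was reversed. Reversed values of the Chd1 line were also those of the Chd1 gene (−0.096 without mock 1 and −0.195 without auxin 2; range −0.195 to 0.225) and, without auxin 2, the lists of cytosolic ribosomal proteins (0.057; range −0.095 to 0.057) and proteasome genes (−0.004; range −0.032 to 0.173), given as the mean of members minus that of other genes and counted as reversed by the direction camera gave. Where that direction stayed, this mean still changed sign in 6 cases, those of signalling (0.022 without auxin 2), cell surface (0.029 without mock 1, 0.04 without auxin 2), DNA replication (0.035 without auxin 1) and proteasome genes (−0.032 without mock 1) in the Chd1 line and of basal transcription in the parental line (−0.008 without mock 1).

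Among single named genes with a library left out 870 values kept their side of the threshold, 349 were no longer called, 1 was newly called and 2, those of Chd1, reversed. Lists without a call as reported became called in the parental line without a filter (mitochondrial ribosomal proteins, adjusted p = 0.00575; remodellers, 0.0107; oxidative phosphorylation and DNA replication, 0.0168 each), with library size alone (transcription factors, 0.041) and with the block (signalling, 0.0227), and in the Iswi line without a filter and with the block (oxidative phosphorylation, 0.002 and 0.0351; remodellers, 0.00174 and 0.041). List calls lost were, without a filter, those of immune (0.0738), cytosolic ribosomal protein (0.145), heat shock (0.173) and stress genes (0.244) in the parental line and of 5 lists in the Chd1 line (0.0725 to 0.0999), with the stricter filter parental heat shock (0.0844) and Ino80 matrix genes (0.0535), also lost with replicates 2 and 3 alone (0.182), and with library size alone Ino80 cytosolic ribosomal proteins (0.0565) and Brd7 immune genes (0.0588). Of list calls with a library left out 212 held, 44 were lost and 2 reversed in camera's direction, and of differences between lines at named genes 295 held and 65 were lost.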

Other observations

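The tests by chromosomal location, of mock levels and of initiator scores were chosen only after the results they bear on had been seen, while that of divergent pairs was not.

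Genes in and next to pericentromeric heterochromatin were prominent among the falls of the Iswi line. Of 38 TSSs tested on the heterochromatic scaffolds of dm3, 18 fell (47.4%) and 0 rose, with a median of −0.77, against 384 of 9823 (3.9%) on the arms away from the centromere. Besides Ucrh, Dbp80 and Alg-2 the falls included CG40042 (2LHet, 168934 to 169083; −1.82 ± 0.16, adjusted p = 1.15e-07), Parp, the poly(ADP-ribose) polymerase gene (3RHet; −1.07 ± 0.22, adjusted p = 0.00352) and the cohesin gene vtd (−0.67), named after their values were seen. Per library the mean log2 CPM of these TSSs lay 0.673 and 0.547 above that of the arms in the mock libraries of the Iswi line and −0.062 and −0.199 from it in the auxin libraries.

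A candidate explanation is that genes in heterochromatin depend on Iswi as a group. As a set the scaffolds were lower in the Iswi line with an estimated correlation between genes (camera adjusted p = 0.000432 over 6 lines), and in the 2 Mb of each arm next to the centromere 77 of 479 TSSs fell (16.1%), 4.13 times the percentage of the rest of the arms (adjusted p = 0.0179 with an estimated correlation). On chromosome 4, which is largely heterochromatic, 22 of 85 TSSs fell (25.9%), with adjusted p = 5.65e-12 at the preset correlation and 0.174 with an estimated one. In the other 5 lines no location was called with an estimated correlation (adjusted p of 0.348 to 0.966), while at the preset one the scaffolds and chromosome 4 lay higher in the Snr1 line (adjusted p = 0.0127 and 0.00319). The hypothesis came from the largest falls, which are part of the sets tested, the width of 2 Mb was chosen with the data at hand, and of the 38 TSSs 28 are of the housekeeping class. How reads with several matches were treated, which matters in repeated sequence, is not given in the sources used here and was not tested.

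The fall of cluster 4 in the Snr1 line, of the housekeeping class with initiator motifs, raised the hypothesis that the initiator may mark other housekeeping TSSs that fall. In clusters 5 to 8 the 431 TSSs with an initiator score of at least 90 had a median of 0.00 and the 4053 others a median of 0.26, a difference of −0.261, and 14.4% against 2.5% fell. The values were consistent with the hypothesis, though the score was not separated from other motifs, expression level or distance to neighbouring genes. In the Brd7 line the difference was −0.127.

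Ino80 acts at nucleosomes that divergent genes can share, and opposite changes of neighbours were looked for. Over 1276 divergent pairs at most 500 bp apart the Ino80 effects of both TSSs correlated with r of 0.045, within the range of 1000 shuffles (−0.084 to 0.086), with 23 pairs called in opposite directions, 25 both higher and 5 both lower, so that the negative correlation of opposite changes was not found. In the Snr1 line r was 0.301.

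Partial loss of a tagged protein before auxin could lower its targets in the mock libraries, and stays open for both Brahma lines. TSSs that fell in the Snr1 line had a median of −0.182 in its mock libraries against the mean of the mock Iswi, Ino80 and Chd1 lines (−0.195 and −0.131 per library). For the Brd7 line the value was −0.096 (−0.148 and −0.07), while the same TSSs stood at −0.291 in the mock Snr1 and −0.234 in the mock Ino80 libraries, a line with no tag on a Brahma protein. The value of −0.096 lies above the bound of −0.1 that had been set to speak against partial loss, and the requirement that both libraries lie above it was added after the value was seen, since 1 of the 2 did not.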
